A study of Mus musculus with 16 samples.

How the data were processed

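Epithelial basal cells of the limbus, the rim between cornea and conjunctiva, and of the cornea were taken from 8 wild-type mice by laser capture microdissection, 300 cells per site and mouse, per the labels' protocols. RNA was extracted, amplified and labelled with biotin, and each of the 16 samples was hybridised to 1 Affymetrix Mouse430_2 array, per the file headers. The letters in the sample titles were read as corneal and limbal, and the number in each title as the mouse. No array was left out of the primary comparison.

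The deposited table held 1 intensity per probe set and array on a linear scale, a signal of the kind that the Affymetrix MAS5 algorithm gives. The algorithm and its software version are not given in the sources used here. Each deposited column of intensity values had a mean of 500.0 after trimming 2% at each end, which shows that the authors had scaled every array to that target. Scaling of this kind equalises the bulk of the signals, so an array with little labelled target has its background and its spiked controls raised with everything else. The table held 45101 probe sets, of which 64 were control probe sets and were kept out of the tests. The array information files gave the scan day, the fluidics station and the fluidics protocol, and were used only for those.

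Values were taken as log2(signal + 89.4), the added constant being the 25th percentile of all values. A log2 difference on this scale understates the change of dim probe sets. Because the trimmed means differed by a factor of 1.00, under the limit of 1.1, no further normalization was applied. Probe sets with a mean log2 value above the 40th percentile were tested, which left 27022. The filter used the mean over all arrays and no group label. In the platform annotation 34958 probe sets had 1 gene symbol and 932 had several. Of the probe sets other than controls, 9160 were not listed there. Among the tested probe sets these numbers were 21880, 619 and 4523. Of the probe sets with a single symbol, 99.4% had an Entrez identifier that was also in the RefSeq gene table. A gene was read from its brightest tested probe set with a single symbol, which gave 13570 genes, and no gene was named from a probe set with several. Probe sets whose identifier ends in _x_at or _s_at can also bind related transcripts. No genome was used, so no coordinates are given.

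Limbal and corneal arrays were compared with limma 3.58.1 in R 4.3.3, with the mouse as a fixed term, a mean-variance trend in the moderated variances and Benjamini-Hochberg adjustment over the 27022 probe sets. The threshold was an adjusted p of 0.05. The pairing comes from the design, in which both captures came from the same 8 animals, with the animal numbered in the title. As a check, the deviations of the 2 arrays of a mouse from their group means correlated across probe sets with a median r of 0.30, against -0.06 for arrays of different mice and 0.33 for arrays of different mice scanned on 1 day. The correlation was above 0.1 in 7 of the 8 mice and 0.03 in mouse 2. Without the mouse in the model, limma called 0 genes. Scan day was the same for both arrays of a mouse, so the mouse term absorbs it, and values within each scan day are given beside the pooled ones.

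The choices of model, filter, constant, gene lists and genes to name were made before the data were examined. Of the fixed gene lists, 30 had at least 5 measured members. They were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, limma's fry, and exact two-sided sign flips of each list's mean difference over the 8 mice were run beside it. The smallest p that the sign flips can give is 0.0078125. The genes named are those past the threshold with the same sign in at least 7 mice, up to 12 per direction by size (or, where fewer than 5 pass in a direction, the 5 with the smallest p, said not to pass), 14 fixed marker genes, and up to 4 members of each described list with the smallest p. Differences are limbal minus corneal, given with the standard error of the fit.

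Alternatives covered the mouse term (statmod 1.5.0 for the random version), the filter, the added constant, quantile normalization and median centring, the variance trend, array weights, a 3' to 5' ratio covariate, the fluidics station, each scan day alone, averaging of a gene's probe sets and leaving out each mouse. The fit without the arrays of scan day 2, the sign-flip test of the lists and the test of a difference between scan days were added after the data were seen.

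The fit was tested on simulated data made from the 27022 probe sets of the limbal and corneal arrays, with 200 of them changed by known amounts. Of the 50 probe sets changed at each size, 0% were called at a log2 difference of 1, 44% at 2, 94% at 3 and 98% at 4, with 2 false calls. With no change at all, 0 probe sets were called. The simulated noise was drawn independently for each probe set. In the real data the members of some lists moved together, with a mean correlation of 0.59 among cytosolic ribosomal proteins. The simulated counts thus do not give the rate of false calls on the real arrays. With the same kind of noise, 30 lists of 25 genes were simulated, 1 of them shifted by 1 log2 unit. Camera at the preset correlation called the shifted list (adjusted p = 1.4e-19) and also called 1 unchanged list. The number of arrays limits the precision, and differences of 1 log2 unit in single probe sets are beyond the reach of this comparison.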

Results

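Gene expression was measured in basal cells of the limbal and the corneal epithelium from 8 mice, 8 arrays per site. The limbus is the region in which the stem cells of the corneal epithelium are thought to reside. The comparison asks which transcripts differ between basal cells of the limbus and of the cornea of the same animals. The arrays had been scanned on 3 days, with mice 1 and 2 on day 1, mice 3 to 5 on day 2 and mice 6 to 8 on day 3.

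The arrays were of unequal quality. The median Pearson correlation between arrays across probe sets was 0.48 within scan day 1, 0.24 within scan day 2 and 0.81 within scan day 3. The 99th percentile of the signal lay between 5171 and 10207 on day 1, between 2443 and 4908 on day 2 and between 14916 and 18165 on day 3. On the corneal array of mouse 5, Krt12, the keratin that marks corneal epithelium, had a log2 signal of 10.02, while the other corneal arrays were at 15.85 or above. The median correlation of that array with the other arrays was 0.05.

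**Figure D1:**
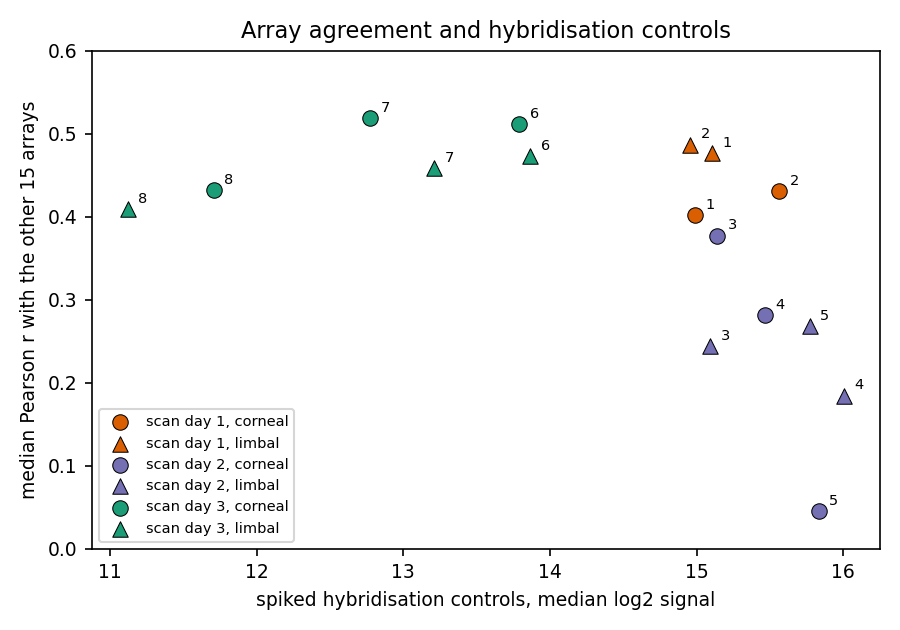
Each point is 1 array, with the median log2 signal of its spiked hybridisation controls on the x axis and its median Pearson r with the other 15 arrays on the y axis. Colours give the scan day, circles corneal and triangles limbal arrays, and numbers the mouse. The 6 arrays of scan day 3 have the lowest control signals, between 11.12 and 13.86, and the corneal array of mouse 5 has the lowest correlation, 0.05.

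17 genes, among them the keratin genes Krt4 and Krt15, were higher in limbal than in corneal captures, and the neuropeptide gene Npy was lower. Krt4, a keratin of non-cornified stratified epithelia such as conjunctiva, had the largest difference (probe set 1438394_x_at). Its mean log2 signal was 12.70 ± 1.80 (SD, n = 8) in limbal and 9.23 ± 1.82 (SD, n = 8) in corneal arrays, a difference of 3.47 ± 0.53 (SE), or 11.1-fold, with an adjusted p of 0.0031 in limma. Krt15, a keratin of basal and stem cells of stratified epithelia (1422667_at), was higher by 2.95 ± 0.57 (adjusted p = 0.018). Both were higher in the limbal array of 7 of the 8 mice. The difference of Krt15 was between 2.60 and 6.63 in mice 1, 2, 6 and 7, which had the largest stromal list differences, and 3.57, -0.77, 0.92 and 0.04 in mice 3, 4, 5 and 8. That of Krt4 was between 1.46 and 6.63 in the former and between -0.38 and 4.75 in the latter. Npy (1419127_at) was at 8.43 ± 1.26 (SD, n = 8) in limbal and 11.25 ± 0.93 (SD, n = 8) in corneal arrays, a difference of -2.82 ± 0.44 (SE), lower in 7 of 8 mice (adjusted p = 0.0031).

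In all, 18 of 13570 genes passed the threshold, 17 higher and 1 lower in limbal cells, from 23 of 27022 probe sets (22 higher and 1 lower). At an unadjusted p under 0.05 there were 911 genes, against 678.5 expected by chance. The calls depended on the model and on single mice: limma called 0 genes without the mouse in the model, 0 after quantile normalization and 0 without mouse 2, with 431, 804 and 822 genes at an unadjusted p under 0.05. The count was 4 without mouse 1, 6 or 7, 8 without mouse 3 and 45 without mouse 8. Within single scan days it was 73 on day 1, which has 2 mice, and 0 on days 2 and 3 (505 and 1363 at an unadjusted p under 0.05).

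Several of the other called genes act in metabolism, matrix turnover and transport. Lpl, which encodes lipoprotein lipase, was higher in limbal cells by 2.96 ± 0.52 and Fa2h, a fatty acid hydroxylase, by 2.54 ± 0.49. Slc5a1, a sodium-glucose cotransporter, was higher by 2.32 ± 0.42, and Enpp3, an ectonucleotidase, by 3.35 ± 0.55. The difference of Enpp3 was between 2.85 and 7.06 in mice 1, 2, 6 and 7 and between -0.19 and 2.42 in the others. The matrix metalloproteinase gene Mmp2 and the inhibitor gene Timp2 were higher by 2.85 ± 0.53 and 2.45 ± 0.45. The difference of Mmp2 was between 2.78 and 6.61 in mice 1, 2, 6 and 7 and between 0.52 and 1.47 in the others, and the mean difference of the stromal gene list described further on was between 1.45 and 3.25 in the former and between 0.06 and 0.50 in the latter. Lpl, Fa2h, Slc5a1 and Mmp2 were higher in 8 of 8 mice, Enpp3 and Timp2 in 7. In other called genes these sets of mice overlapped. For Slc5a1 the difference was between 0.80 and 3.01 in mice 1, 2, 6 and 7 and between 1.30 and 3.43 in the others. For Lpl it was 0.24 to 6.57 and 0.12 to 3.52, and for Timp2 2.51 to 4.01 and -0.23 to 3.37. The others are mice 3 to 5, scanned on day 2, and mouse 8, with the smallest differences. Throughout, a split by the stromal list thus cannot be told apart from one by array quality as far as mice 3 to 5 are concerned. The arrays of mouse 8 were not dim, with a 99th percentile of the signal of 16077 (corneal) and 16330 (limbal). For mouse 8 the split cannot be told apart from its small differences in general. Lyz1, a lysozyme gene, was higher by 2.84 ± 0.55, Lgi2 by 2.58 ± 0.50 and Rbms3, which encodes an RNA-binding protein, by 2.28 ± 0.45, each in 7 mice. The difference of Lyz1 was between 4.12 and 5.66 in mice 1, 2, 6 and 7 and between -0.68 and 1.53 in the others, and stromal and immune gene lists were higher in the same captures. The remaining called genes outside the lists were Wfdc18 (2.23), the mast cell protease gene Cpa3 (2.21) and the cathepsin S gene Ctss (2.08), named after their values were seen. All 18 called genes kept their sign in the mean difference of each scan day, with a median absolute difference of 3.71 on day 1, 1.62 on day 2 and 3.11 on day 3. These days are part of the data on which the genes were called. Krt4, Lpl, Enpp3, Mmp2, Timp2, Lyz1, Lgi2 and Rbms3 had other tested probe sets, and none of those passed.

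**Figure D2:**
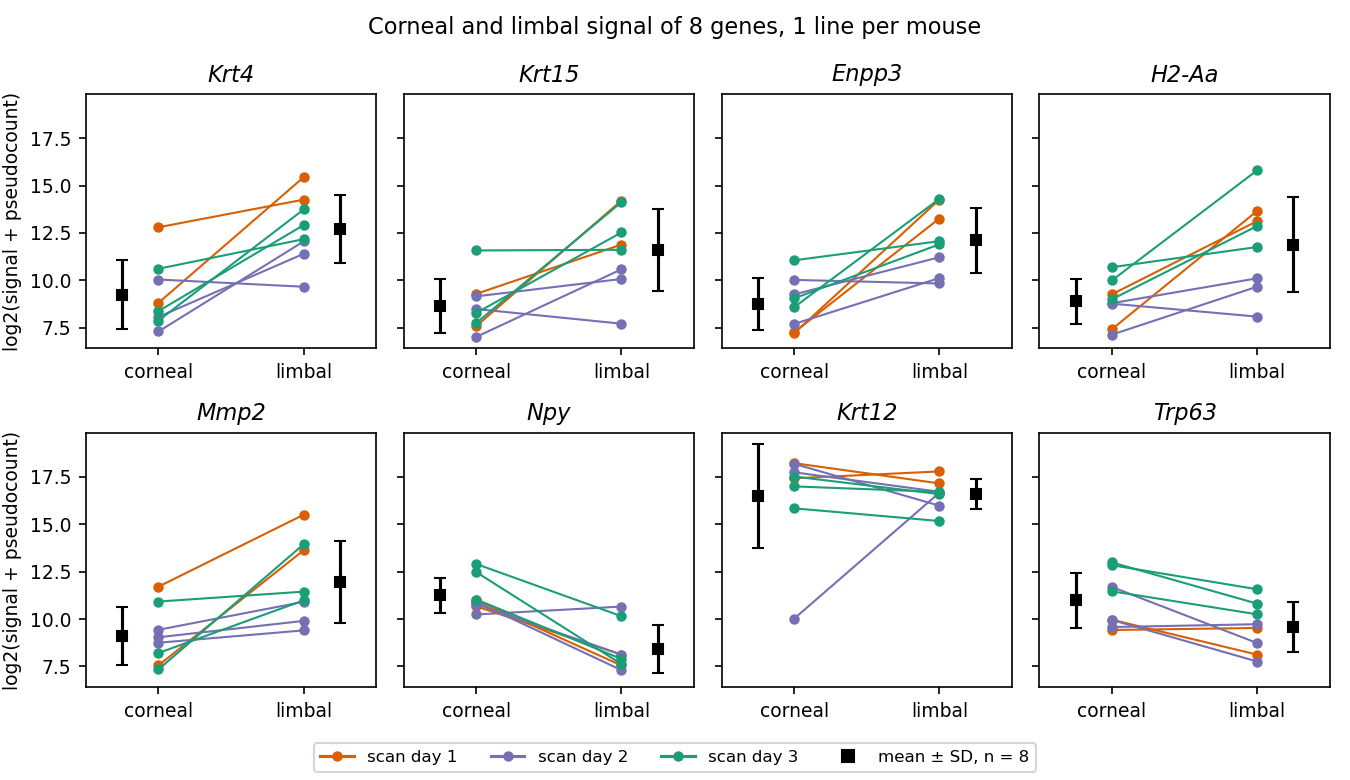
Log2 signal of 8 genes in the corneal and the limbal array of each mouse, 1 line per mouse, coloured by scan day. Black squares and bars give the mean and SD over 8 arrays. Krt4 averaged 12.70 in limbal and 9.23 in corneal arrays and Npy 8.43 and 11.25, while Krt12 averaged 16.60 and 16.50 with the corneal array of mouse 5 at 10.02.

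Apart from Npy no gene was called as higher in corneal cells. The next genes by p in that direction did not pass. Epb41l4a differed by -1.96 ± 0.44 (adjusted p = 0.068) and Ppp1r3c, a regulator of glycogen metabolism, by -1.82 ± 0.43 (adjusted p = 0.094), both lower in the limbal array of 8 of 8 mice. Nusap1, a spindle protein gene, differed by -1.94 ± 0.44 (adjusted p = 0.070) and Fam169a by -1.87 ± 0.46 (adjusted p = 0.12), each lower in 7 mice. All 4 passed with array weights (adjusted p between 0.00054 and 0.014), a fit that leans on mouse 8, and Nusap1 also with the mouse as a random term (adjusted p = 0.041). Leaving out a mouse brought Epb41l4a past the threshold without mouse 4 (0.035) or 8 (0.034), and Ppp1r3c (0.034) and Fam169a (0.011) without mouse 5.

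Genes of corneal epithelial differentiation did not pass as a list over all 8 mice. No difference of Krt12 was detectable on its brightest probe set. Of the 24 measured members, 14 were lower in limbal cells, and 0 were called over all genes. The median difference was -0.20 (camera adjusted p = 0.11; adjusted p = 0.75 with an estimated correlation). The list's mean difference was 1.59 in mouse 5, and without mouse 5 its median was -0.65 and camera called it lower (adjusted p = 0.00039). It was also called without mouse 1 (adjusted p = 0.038), within scan day 3 (0.00068), with array weights (0.0010) and without scan day 2 (0.011). These calls were made by camera at the preset correlation. Adjusted over the list alone, 4 were lower (Ppp1r3c, Ehf, Slurp1 and Pax6) and 1, the tight junction gene Cldn4, was higher. Krt12 differed by 0.10 ± 1.07 with a 95% interval from -2.07 to 2.28, and by -0.83 without mouse 5. Krt12 was lower in the limbal array of 6 of 8 mice. The other tested probe set of Krt12 did not pass, and its signal was lower in the limbal array of the same 6 mice. Its limbal and corneal signals were 6713 and 54422 in mouse 3 and 9379 and 136516 in mouse 6. They were 60599 and 29061 in mouse 1 and 7036 and 251 in mouse 5, the mice with the higher limbal signal. Equal Krt12 at both sites is thus not shown. Aldh3a1, a corneal crystallin enzyme, differed by -0.74 ± 0.73 and by -1.54 without mouse 5. The gap junction gene Gja1 differed by -0.76 ± 0.57, with -3.93 in mouse 3 and between -2.10 and 1.87 in the other mice. Krt5 differed by -0.18 ± 0.64, by -0.90 without mouse 5 and by 0.24 after quantile normalization. Pax6, the eye transcription factor gene, differed by -1.15 ± 0.42 and was lower in 8 of 8 mice, with an adjusted p of 0.55 over all genes. Krt14, a basal keratin, differed by 0.83 ± 0.41 and was higher in 7 mice (adjusted p = 0.77).

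Among proposed markers of limbal and epithelial stem cells the members went in opposite directions. Of 27 measured genes, 15 were higher and 12 lower in limbal cells, with a median difference of 0.17 (camera adjusted p = 0.18). Camera called the list within scan day 1 alone. Krt15 and the intermediate filament gene Vim were called over all genes, and 2 other tested probe sets of Vim did not pass. Adjusted over the list alone, 6 were higher (Krt15, Vim, Spon1, Krt19, Apcdd1 and Gpha2) and 1, Trp63, was lower. Trp63, the p63 gene of stratified epithelia, differed by -1.42 ± 0.41 and was lower in 6 of 8 mice (adjusted p = 0.29 over all genes). The transporter gene Abcg2 differed by -0.97 ± 0.46 and the integrin gene Itga9 by -0.68 ± 0.49. Itga9 was lower in 4 of 8 mice, with a difference of -3.63 in mouse 5 and between -2.92 and 1.14 in the others. Fry's test for change in either direction called 3 of the 30 lists, this one (adjusted p = 0.014), the cell cycle list (0.015) and the conjunctival list (0.022).

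Genes of the conjunctiva were higher in limbal cells as a list, led by keratins. The list of conjunctival epithelium and goblet cells had 11 of its 16 measured members higher, with a median difference of 0.63 (camera adjusted p = 1.6e-05; adjusted p = 0.34 with an estimated correlation). Krt4 was called over all genes, and adjusted over the list alone 6 were higher, all keratins (Krt4, Krt8, Krt19, Krt13, Krt7 and Krt6a). The remaining keratin of the list, Krt18, differed by -0.46 ± 0.44 and was higher in 3 of 8 mice. Krt8 differed by 1.78 ± 0.42 in 8 of 8 mice, Krt13 by 1.88 ± 0.51 and Krt19 by 1.83 ± 0.49, each in 7 mice (adjusted p between 0.10 and 0.22 over all genes). The goblet cell genes Tff1, Tff2 and Spdef differed by 0.07, -0.07 and -0.23. The list's mean difference was 1.64 on scan day 1, 0.18 on day 2 and 0.95 on day 3. It was between 0.74 and 2.08 in mice 1, 2, 6 and 7, where the stromal list differed by 1.45 to 3.25, and between -0.38 and 0.60 in the others, where the stromal list differed by 0.06 to 0.50.

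Genes of stromal keratocytes and fibroblasts were higher in limbal captures as a list. Of 26 measured members, 25 were higher, with a median difference of 1.14 (camera adjusted p = 2.3e-18; adjusted p = 0.14 with an estimated correlation). The list's mean was higher in 8 of 8 mice, by 1.29 ± 1.24 (SD, n = 8). Col1a2, a collagen I gene, differed by 2.91 ± 0.57 and Vim by 2.83 ± 0.60, both called over all genes and both higher in 6 mice. Adjusted over the list alone 14 were higher, among them Dcn, which encodes decorin (2.01 ± 0.48), and Ogn, which encodes osteoglycin (1.91 ± 0.45). The keratocyte gene Kera differed by 0.21 ± 0.44. The list's mean difference was 2.11, 0.32 and 1.72 on scan days 1, 2 and 3.

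Immune and muscle genes were also higher as lists. Of 19 measured immune cell genes, 15 were higher, with a median difference of 0.40 (camera adjusted p = 0.0062; adjusted p = 0.48 with an estimated correlation). H2-Aa, which encodes an MHC class II chain, was called (8.01-fold higher, log2 SE 0.53, higher in 7 of 8 mice, adjusted p = 0.0097), and a further probe set of H2-Aa passed. The difference of H2-Aa was between 3.86 and 6.24 in mice 1, 2, 6 and 7, the mice with the largest stromal list differences, and between -0.68 and 2.53 in the others. Adjusted over the list alone, H2-Aa, the macrophage receptor gene Csf1r (2.09 ± 0.62) and the complement gene C1qb (1.38 ± 0.48) were higher, C1qb in 7 mice and Csf1r in 4, with a mean difference of -0.93 for Csf1r on scan day 2. The immune list's mean was higher in 5 of 8 mice and differed by 0.92, -0.10 and 0.94 on scan days 1, 2 and 3. Of 16 genes of muscle and pericytes, 13 were higher, with a median of 0.60 (camera adjusted p = 0.0068; adjusted p = 0.48 with an estimated correlation), and the myosin gene Myh1 was the only one past the threshold adjusted over the list alone (2.86 ± 0.69). The muscle list's mean difference was 3.38 in mouse 6 and 1.57 in mouse 5, and between -0.39 and 0.49 in the other mice. Without mouse 6 its median was 0.15 (camera adjusted p = 0.41). For immune genes the adjusted p was 0.081 without mouse 6 and 0.078 without mouse 7.

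Cell cycle genes were lower in limbal cells as a list. Of 35 measured members, 27 were lower, with a median difference of -0.55 (camera adjusted p = 1.0e-05; adjusted p = 0.14 with an estimated correlation), and the list's mean was lower in 7 of 8 mice by -0.45 ± 0.33 (SD, n = 8). No member was called over all genes by limma, and adjusted over the list alone 1, Nusap1, was lower. Rrm2, a ribonucleotide reductase gene, differed by -1.15 ± 0.45, Anln, which encodes anillin, by -0.97 ± 0.39 and the proliferation marker gene Mki67 by -0.94 ± 0.41. The list's mean difference was -0.19, -0.41 and -0.65 on scan days 1, 2 and 3.

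2 further lists were called with no member past the threshold, over all genes or adjusted over the list alone. Genes of the cornified envelope and epidermal differentiation had 20 of 25 members higher, with a median of 0.49 (camera adjusted p = 0.011; adjusted p = 0.50 with an estimated correlation). Flg, which encodes filaggrin, differed by 1.60 ± 0.59, higher in 4 of 8 mice, and by 0.82 without mouse 7. The protease inhibitor gene Spink5 differed by 1.55 ± 0.58, Csta1 by 1.02 ± 0.47 and Sprr2d by 0.98 ± 0.43. Spink5 had a difference of 5.97 in mouse 7 and between -3.14 and 3.58 in the other mice. Mouse 7 had the largest difference of the cornified list, 2.84, and without mouse 7 its median was 0.21 (camera adjusted p = 0.66). Genes of the unfolded protein response and secretion had 19 of 27 members higher, with a median of 0.29 (camera adjusted p = 0.039; adjusted p = 0.48 with an estimated correlation). Xbp1, a transcription factor gene of that response, differed by 1.24 ± 0.42, Dnajb9 by 1.11 ± 0.40, Chac1 by 1.09 ± 0.42 and Herpud1 by 1.04 ± 0.41. Camera's adjusted p for the unfolded protein response list was above the threshold without mouse 1, 2, 5, 7 or 8, reaching 0.25 without mouse 2.

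With an estimated correlation 0 of the 30 lists were called, against 7 with the preset one, and fry's directional test and the exact sign flips called 0 after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 these tests had 3, 4 and 4 lists. For the stromal list the exact sign-flip p was 0.0078, the smallest possible with 8 mice, and 0.23 after adjustment.

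**Figure D3:**
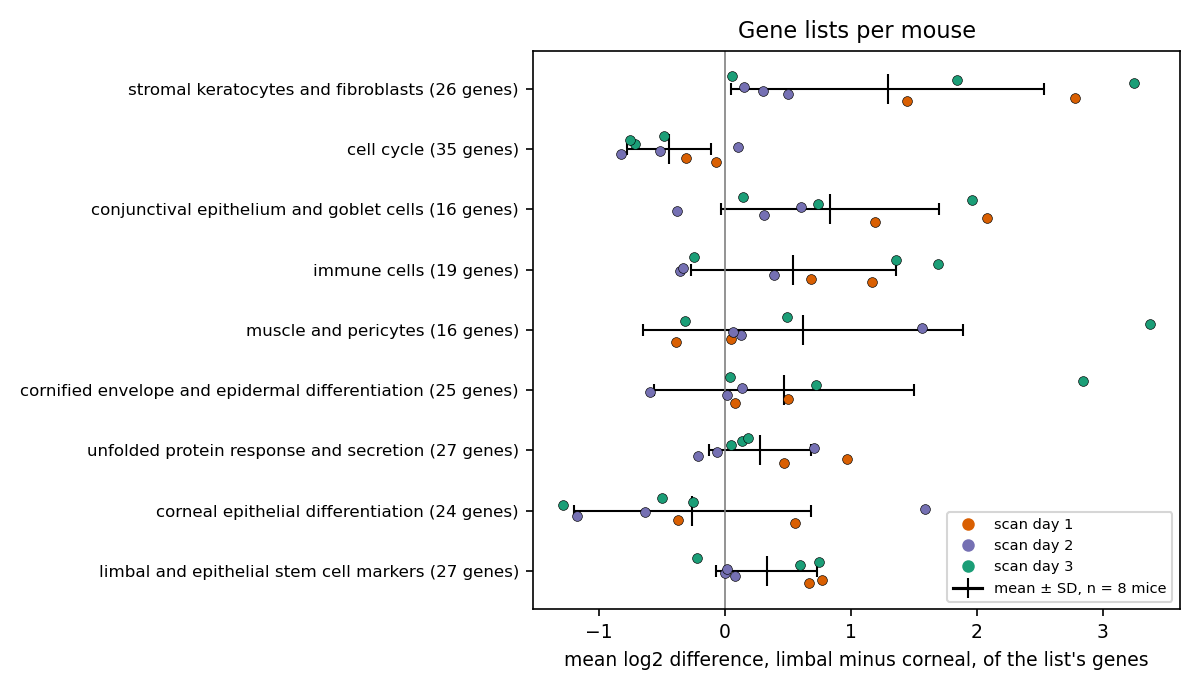
Mean log2 difference, limbal minus corneal, of each gene list in each mouse, coloured by scan day, with the mean and SD over 8 mice as black marks. The 7 upper lists are those called by camera at the preset correlation. The stromal list lies above 0 in all 8 mice, between 0.06 and 3.25, and the cell cycle list below 0 in 7.

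The other lists were not called by camera. Lists with a camera adjusted p between 0.11 and 0.37 were immediate early and heat shock genes (median 0.30), the proteasome (-0.17), melanocytes and pigment epithelium (0.25), the Wnt pathway (-0.16) and the respiratory chain (0.12). Those above 0.4 with a median above 0 were interferon response and MHC class I (0.05), cholesterol biosynthesis (0.13), cytokines and innate defence (0.03), the Notch pathway (0.04), glycolysis (0.12), retinoid metabolism and signalling (0.06), vascular and lymphatic endothelium (0.05), EGF receptor ligands and receptors (0.03), and the TGF-beta and BMP pathway (0.23). Those with a median below 0 were antioxidant and detoxification genes (-0.04), basement membrane and hemidesmosomes (-0.10), cytosolic ribosomal proteins (-0.03) and a control list of Sertoli and germ cell genes (-0.12). Median and test differed in sign for cell junctions (0.04), lens and retina (0.05) and nerve and Schwann cells (-0.0015).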

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

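The tests of hybridisation controls, of co-variation among stromal genes and of 500 and of single genes in mouse 8 were chosen only after the result was seen, and the others before. The probe sets called between limbal and corneal arrays were set against chance. Among 100 splits that swap limbal and corneal within mice, only the real one called as many as 23 probe sets, so that 1 of 100 reached that count, and the highest of the others called 13. Of the other splits, 92 called 0. Chance is thus an unlikely source of the count in the primary fit. Only 100 of the 128 possible splits were run, and 0 genes were called after quantile normalization or without mouse 2.

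Some single arrays lay far from the other 7 of their group. Of 119 groups examined, 11 had such an array, and chance gives about 5%. The corneal array of mouse 5 accounts for 4 of them, with low log2 signals of Krt12 (10.02), Aldh3a1 (8.60) and Krt5 (8.15) and a low 3' to 5' log2 ratio of the control transcripts (0.17). The corneal array of mouse 8 was high for Lyz1 (11.77) and Lgi2 (10.19). The limbal array of mouse 4 was low for Lgi2 (7.13) and Chac1 (7.36). Slc5a1 was high on the limbal array of mouse 7 (12.02) and Nusap1 on the corneal array of mouse 2 (11.43). The cornified envelope list had a difference of 2.84 in mouse 7, where the next mouse had 0.72.

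The 6 arrays of scan day 2 correlated little with the other arrays. The spiked hybridisation controls, which do not come from the cells, were higher there than on scan day 3 by 2.81 log2 units (exact permutation of the 3 and 3 mice, two-sided p = 0.10, the smallest possible), and the lowest array of day 2 lay 1.23 above the highest of day 3. The scaling of every array to 1 trimmed mean also undoes a dim scan, so the height of these controls does not exclude a failed hybridisation or scan. Little labelled target, whose weak signal the scaling raises, may be the reason. Day 2 exceeded day 1 by only 0.40, although day 1 arrays correlated better, so this leaves part of the pattern open, and no biological explanation was tested.

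Stromal and fibroblast genes were higher in the limbal arrays. A weaker target on the corneal array of each mouse would not give this in mice whose limbal array had the weaker target. In 4 of those 4 mice the list was still higher in the limbal array. Because it was higher in all 8 mice, this count was fixed in advance. The controls differed by only 0.12 and 0.07 log2 units in mice 1 and 6, and by 0.54 and 0.44 in mice 4 and 7. A weaker corneal target is thus left undecided. The differences of the list's members correlated across mice with a mean of 0.29. Of 1000 random lists matched on mean expression, 0 were as high (median 0.016, 95th percentile 0.091). Lists that camera did not call also had high mean correlations. They were 0.59 for cytosolic ribosomal proteins, 0.36 for the respiratory chain and 0.23 for corneal epithelial differentiation. Co-variation therefore does not mark admixed tissue, and whether some limbal captures held stromal tissue is not decided by it. Median limbal signals were 5447 for Col1a2 and 5520 for Col3a1, against 499 and 810 in corneal arrays. Expression of these genes by limbal basal cells themselves would also move them together, so it stays open, and Vim is also among the stem cell markers. The corneal arrays of mice 1 and 8 had Col1a2 signals of 7883 and 5577, so high stromal signals are not limited to limbal captures.

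The 2 arrays of mouse 8 correlated at r = 0.94, more than those of any other mouse, and the limbal one had been run with another fluidics protocol. Of 45 genes called without mouse 8, 26 had the other mice's sign in mouse 8, and of the 500 genes with the largest mean difference in mice 6 and 7, 326 had that sign (65.2%), though genes are not independent. Single genes differed by far more than the SD of 0.53 of all differences in mouse 8, among them Npy (-3.14), Krt4 (1.56), Aldh3a1 (-1.53) and Tyrp1 (3.75, 3.56 and 1.07 in 3 probe sets), which speaks against 1 RNA on both arrays, but they were picked for their size and no repeat hybridisation gives the technical spread, so it is not excluded. Limbal and corneal cells mixed in the captures of mouse 8 might shrink its differences, and the median ratio to mice 6 and 7 over the 45 genes was 0.014, while its corneal and limbal arrays both had high signals of Myh1 (66736 and 69497), Myh4 (56661 and 77247), Lpl (37399 and 40625) and Vim (9040 and 5892), where Myh1 was at 23 and 324 on the corneal arrays of mice 6 and 7. Set against all other mice, over the genes called without the mouse in question, the ratio was 0.018 for mouse 8. It was -0.095 for mouse 4 over 19 genes and 0.22 for mouse 5 over 27, at array correlations of 0.25 and 0.15. A low ratio is thus not particular to mouse 8 and settles neither explanation. A small limbal difference in mouse 8 stays open as untested.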

How the results depend on the processing

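The fit without the arrays of scan day 2 was chosen after seeing the data. It called 16 genes, 10 of them among the 18. Without the replicate block (the mouse) 0 probe sets and 0 genes were called, with 858 and 431 at an unadjusted p under 0.05, and 6 lists; with the mouse as a random block the counts were 23 and 17, 15 of the genes shared. Quantile normalization gave 0 and 0 (1594 and 804 unadjusted), a filter at the 60th percentile 8 and 8, a constant of 1 gave 4 and 4, the fluidics station as a term 5 and 5 (only 2 of the genes shared) with 4 lists, and the mean of a gene's probe sets 2 genes. Array weights gave 117 and 83, 16 of the genes shared, with 57 higher and 26 lower in limbal cells, and its largest weights were on the arrays of mouse 8, so that fit leans on the mouse with the smallest differences (median absolute difference 0.31). Within scan day 1 the counts were 104 and 73 (14 shared), within day 2 they were 0, 0 and 0 lists, and within day 3 they were 0 and 0 with 11 lists. Leaving out 1 mouse gave 0 to 52 probe sets, 0 to 45 genes and 4 to 10 lists. The cause was not tested, apart from fewer mice or probe sets where the setting has them. In mice 1, 7 and 8 the corneal array was run on station 2 and the limbal one on station 1. Both arrays of every other mouse shared a station. With the station as a term, the site difference therefore comes from mice 2 to 6 alone. Site and station are thus partly confounded in the primary comparison too. With no filter, median centring, a constant at the median, no variance trend or the 3' to 5' ratio covariate, 15 to 21 genes were called, at least 15 of them among the 18. Exact sign flips were run for the named genes alone, which were partly picked by p on the same data, and give no independent support.

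With camera at the preset correlation, the stromal list lost its call within day 2 and the cell cycle list within days 1 and 2, and neither turned direction; both lost it with an estimated correlation, fry and the sign flips. The median difference over all genes stayed within 0.04 of 0 except within day 1 (0.13). Differences that turned sign were those of Krt12 with array weights (-0.38), the ratio covariate (-0.013), within day 1 (-0.35) and day 3 (-0.63), with the mean of probe sets (-0.49), without scan day 2 (-0.52) and without mouse 5 (-0.83), the range without 1 mouse being -0.83 to 0.43. Krt5 turned with quantile normalization (0.24), within day 1 (0.63) and day 2 (0.55), and without mouse 3 (0.03), 4 (0.0017) or 6 (0.11), with a range of -0.90 to 0.11. Within day 1 Gja1 (0.59), Rrm2 (0.13), Myh4 (-1.73), Flg (-0.35), Sprr2d (-0.15) and the muscle list (-0.17) turned, within day 2 Aldh3a1 (0.021), Csf1r (-0.93), the cornified envelope list (-0.032) and camera's direction of the immune list, whose median was 0.32, and within day 3 Itga9 (0.065). The cause was not tested. Differences of about 1 log2 unit are below what 8 mice with these arrays resolve, and the signals of scan day 2 were the lowest at the 99th percentile.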

Other observations

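The tests of a difference between scan days, the counts of genes with 1 sign in all mice and the lists of genes named here were chosen only after the data were seen. The gene of the thyroid hormone carrier transthyretin, Ttr, differed between limbal and corneal arrays by scan day, with a day 1 value that rests mainly on mouse 1. For the probe set 1455913_x_at the difference was -5.33 on day 1, -0.51 on day 2 and 5.22 on day 3 (limma adjusted p = 0.012 for a difference between days), and for 1459737_s_at it was -2.88, -1.68 and 4.42 (adjusted p = 0.035). On day 1 the 2 mice had -8.16 and -2.50 for the former and -5.51 and -0.25 for the latter, and a further Ttr probe set, 1454608_x_at, had -9.59 and 0.64 and did not pass (adjusted p = 0.36). Ceacam1, which encodes a cell adhesion molecule, differed by 5.98, -0.81 and 1.27 (probe set 1425538_x_at, adjusted p = 0.035), and 4 other Ceacam1 probe sets, with day 1 differences between 1.11 and 4.98, did not pass (adjusted p between 0.80 and 0.89). These 3 probe sets were the only ones past the threshold in that test. Ptgds, a prostaglandin D synthase gene, had day 3 differences of 4.37 and 2.23 in its 2 probe sets, and the pigment gene Tyrp1 3.82, 3.73 and 0.08 in its 3, and none of these passed it (adjusted p between 0.35 and 0.95).

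Members of further lists that were not called as a whole passed adjusted over the list alone. The receptor gene Notch2 of the Notch list was higher in limbal cells by 1.66 ± 0.43 in 8 of 8 mice, and the interferon-induced gene Ifitm1 by 2.23 ± 0.56 in 7. Of the antioxidant list, the glutathione transferase gene Mgst1 was higher by 2.51 ± 0.61 in 7 mice, and Gclm, of glutathione synthesis, differed by -1.56 ± 0.42, lower in 8 of 8. Among EGF receptor ligands and receptors, Ereg, which encodes epiregulin, was higher in limbal cells by 1.62 ± 0.47 and the feedback inhibitor gene Errfi1 by 1.16 ± 0.46, each in 7 of 8 mice, while Epgn, which encodes epigen, differed by -1.25 ± 0.43 and was lower in 8 of 8 (limma adjusted p between 0.11 and 0.64 over all genes for these 7 genes). In the Wnt list Dkk3, which encodes a Dickkopf family protein, differed by -1.39 ± 0.42, lower in 8 of 8 mice, without passing (adjusted p = 0.33 over all genes).

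Genes with the same sign in all 8 mice numbered 161, with 78 higher and 83 lower in limbal cells, where independent signs would give 106. Of the 128 splits that swap sites within mice, 9 gave as many, and the highest of the others gave 266, so the number of such genes does not stand apart from chance.

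The non-coding X-linked transcript Xist (1436936_s_at) had signals between 16663 and 33512 on the 6 arrays of scan day 3. On the other arrays they lay between 83, on the corneal array of mouse 5, and 12381. The Y-linked gene Eif2s3y (1417210_at) was between 4.1 and 80 on scan day 3 and between 31.1 and 600.8 on the others. Its limbal and corneal signals were 78 and 514.8 in mouse 3 and 44.6 and 600.8 in mouse 4. No sex was read from these signals, as the scan days also differ in array quality.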
